A study of Mus musculus with 10 samples.

How the data were processed

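The libraries were made from genomic DNA of CH12F3-2 cells carrying the mTKO guide library, per the labels' protocols, by amplifying the guide cassette. The labels also list the source as transcriptomic and the molecule as total RNA, which these protocols contradict. The deposited values are raw read counts per guide of 20 bases, in 1 file per library. A guide without a read is written as missing and was read here as 0 counts. The submitters' processing notes name Bowtie 0.12.1, and the counting settings and the genome build are not given in the sources used here. Of 89880 guides compared with a GRCm38 gene table, 99.7% lay inside the named gene. That table was used for names (18509 symbols matched) and this check alone.

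The library targets 19461 genes, 94.0% of them with 5 guides. Its 418 control guides (279 against LacZ, 76 against EGFP and 63 against luciferase) were not treated as a gene. There are 25 gene names that a spreadsheet had turned into dates, of which 2 hold 10 guides and so merge genes, and none of these is named in the text. No read was counted for 125 guides at T0 and for 276 to 468 guides in a T9 library.

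Counts were summed over the guides of each gene and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test, with TMM scaling, the default low-count filter (minimum 10, total 15) and Benjamini-Hochberg adjusted p below 0.05. All 9 T9 libraries entered the fit with group as the only term, in 3 comparisons, and 19460 genes were tested. Guides were tested likewise (93530). The 24 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. T9 unsorted libraries were compared with T0 as log2 ratios of CPM after TMM with a prior of 1 CPM, and a list's median was placed among 10000 random lists drawn within 20 bins of T0 abundance. These tests, the lists, the rule for named genes and the alternatives not marked otherwise below were chosen before the data were examined.

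The named genes were, per comparison, those past the threshold with at least 3 guides, the same direction in all 3 letters and in at least 75% of guides, up to 8 per direction by fold. Added were list members past the threshold (up to 6 per list) and 22 genes fixed whatever their values, Fam72a among them. For T9 against T0, genes with at least 3 guides and 100 reads at T0 were used, with all guides and all 3 libraries changed the same way, up to 8 per direction, plus Trp53. Not every gene this rule names is printed. Genes past the threshold under the replicate block alone were picked after their values were seen, by the same rule or from the lists.

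The titles give groups the same letters A, B and C. Deviations of libraries from their group means, over genes, correlated with r between 0.46 and 0.65 in the 9 pairs of the same letter and between -0.35 and -0.19 in the 18 pairs of different letters. The letters were therefore taken to pair the libraries, from the data and not from a statement in the labels, and the fit with the letter as a block is printed where it changes a call. The block lowered the biological coefficient of variation from 0.0969 to 0.051. Without it, 86, 184 and 448 of 19460 genes had an unadjusted edgeR p below 0.05. These were for IgA-negative against unsorted, IgA-positive against unsorted and between the gates. Each is a share under 0.05, so the fit without the block was conservative.

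Alternatives were DESeq2 1.42.0, library totals, TMM over olfactory receptor genes, no filter, guides with under 30 T0 reads removed, the block with and without a guide GC correction, only the groups compared, the most abundant guide removed, guide z values combined per gene, a rotation test (fry) over guides, and each library left out. Thinning to the lowest total and alternatives to the blocked fit were added after seeing the data. The gene test was tested on simulated counts for 19456 genes with 200 changed. For IgA-negative against IgA-positive it recovered 0 of 68 genes changed 1.2-fold, 34 of 66 changed 1.5-fold and 65 of 66 changed 2-fold without the block, and 27, 65 and 66 with it. Unchanged genes made up 0 of its 99 calls without the block and 12 of 170 with it. All groups in these counts shared 1 dispersion per guide. Draws of that kind gave less spread than observed (log2 variance after group and letter means) in both gates. It was 0.0123 against 0.014 in IgA-negative and 0.0125 against 0.0172 in IgA-positive libraries, so the recovery may be overstated. Genes without effect in all 9 libraries, unsorted ones included, were simulated in 20 draws for the correlation between comparisons, whereas the plan had kept the observed unsorted libraries, which would leave out their shared error. The letter effects and the dispersions of the blocked guide fit were kept, and r between simulated libraries of the same letter was 0.59 to 0.65, against 0.45 to 0.65 observed. A second set of 20 draws, added after seeing the data, scaled the dispersions of each group to its observed spread (by 0.195, 1.24 and 1.70 for unsorted, IgA-negative and IgA-positive libraries). In these, the test called at most 0 genes in any comparison without the block, and with it at most 0, 1 and 2 genes for IgA-negative against unsorted, IgA-positive against unsorted and between the gates.

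Totals of 8569951 to 37627717 reads set the precision. Reads carry no molecular identifiers, so counting error understates the error, and the spread between libraries was used. The 1 T0 library has no replicate, and a library of the plasmid pool was not used here.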

Results

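Guide abundance was measured by sequencing the guide cassettes amplified from genomic DNA of CH12F3-2 cells, a mouse B-cell line that switches from IgM to IgA when stimulated. The cells carried a pooled knockout library of 94528 guides against 19461 genes, with 418 control guides against LacZ, EGFP and luciferase. After 3 days with the C.I.T. cocktail, a mix used to induce switching to IgA through CD40, interleukin-4 and TGF-beta, cells were sorted by surface IgA. The 10 libraries were 3 of IgA-negative cells, 3 of IgA-positive cells and 3 of unsorted cells, all labelled T9, and 1 labelled T0 from untreated cells. Library totals were 8706822, 8860777 and 10668344 reads in the IgA-negative gate (replicates A, B and C) and 8569951, 9789521 and 8791382 reads in the IgA-positive gate. They were 17245506, 17054687 and 16760324 reads in unsorted cells and 37627717 reads at T0. The median guide had 77 to 96 reads in a sorted library, 150 to 154 in an unsorted library and 345 at T0. Folds below are of guide reads summed per gene, errors are standard errors of the log2 fold, and n is 3 libraries per group unless stated.

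The comparison of the IgA-negative with the IgA-positive gate asked which knockouts were enriched among cells that had not switched. Guides against Ung, a uracil-DNA glycosylase, were 2.38-fold more abundant in IgA-negative cells (log2 fold 1.25 ± 0.15, n = 3, adjusted p = 0.000373). The genes named here are not all that passed. Of 9 measured genes of uracil excision and related steps, 2 rose, Ung among them, and 7 did not pass, both over all genes and adjusted over the list alone. The list's median log2 fold was 0.03 and its mean 0.35, and the list as a set was higher (camera adjusted p = 2.06e-14). Among 8 mismatch repair genes, 3 rose, Msh6 among them (log2 fold 1.12 ± 0.12, adjusted p = 0.000125), and 4 passed when adjusted over the list alone. Pms2 had a log2 fold of 0.60 ± 0.14 (adjusted p = 0.169). With the replicate letter as a block its value was 0.61 ± 0.07 (adjusted p = 4.08e-09). The mismatch repair list had a median of 0.41 (camera adjusted p = 4.74e-25).

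Fam72a, the gene in the study's title, was 1.61-fold more abundant in IgA-negative than in IgA-positive cells (log2 fold 0.69 ± 0.11, n = 3, adjusted p = 0.0124). Its guides had 49.9 ± 2.59 CPM (reads scaled to library size) in IgA-negative cells, 42.2 ± 1.66 in unsorted cells and 31.1 ± 2.38 in IgA-positive cells (SD, n = 3). The log2 difference between the gates was 0.49, 0.74 and 0.82 for replicates A, B and C, and 5 of 5 guides were higher in IgA-negative cells. The 5 guides lie between bases 131528733 and 131533931 of chromosome 1, in the coordinates of the files, which name no genome build. The strongest was AACACAGGATGGATACGCAT, with a log2 fold of 1.29. The call was lost without IgA-positive replicate B (adjusted p = 0.0776) or C (0.0724), and without IgA-negative replicate B (0.0707) or C (0.116). The Fam72a log2 fold in those fits was between 0.64 and 0.69, and adjusted p over its alternatives ran from 2.52e-07 with the replicate block to 0.156 with a rotation test over guides.

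Guides against receptors and transducers of the cocktail's cytokines were enriched in IgA-negative cells. Tgfbr2 and Tgfbr1, the TGF-beta receptor chains, had log2 folds of 1.35 ± 0.19 (adjusted p = 0.0029) and 0.76 ± 0.09 (adjusted p = 0.000427). These were the 2 of 8 activating TGF-beta pathway genes that rose, and 5 passed when adjusted over the list alone. The list's median was 0.33 (camera adjusted p = 2.64e-19), with 5 genes rising under the replicate block, Smad2, Runx1 and Runx3 being added. Smad4 had a log2 fold of 0.22 and did not pass. Of 5 interleukin-4 receptor genes, Jak1 (0.65 ± 0.13, adjusted p = 0.0458), Stat6 (0.49 ± 0.09, adjusted p = 0.0458) and Il4ra (0.45 ± 0.08, adjusted p = 0.022) rose, and 4 passed when adjusted over the list alone. Leaving out 1 library ended the call of Jak1 in 4 of 6 fits, of Il4ra in 5 of 6 and of Stat6 in 6 of 6. The interleukin-4 list had a median of 0.49 (camera adjusted p = 4.74e-25), and Il2rg passed under the block (0.60 ± 0.09, adjusted p = 1.78e-06, against 0.068 without it). Cd40 had a log2 fold of 0.29 and did not pass, and 0 of 14 activating genes of CD40 and NF-kappaB passed by edgeR (list median -0.01, camera adjusted p = 0.983).

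Other genes that rose were the transcription factor genes Batf (1.14 ± 0.14, adjusted p = 0.000373) and Junb (0.90 ± 0.10, adjusted p = 0.000104), and Ric8, a chaperone of G protein alpha subunits (1.11 ± 0.12, adjusted p = 0.000104). Of 19 growth suppressor genes, 1 passed without the block. Samhd1, which breaks down deoxynucleotides, was the only member of 10 nucleotide pool genes to pass without it (0.62, adjusted p = 0.0314). Under the block, the PHD finger gene Phf14 (-0.54 ± 0.06, adjusted p = 4.08e-09, against 0.0574 without it) and the Mediator gene Med16 (-0.51 ± 0.08, adjusted p = 6.02e-06, against 0.0574) fell. Zc3h12c, Cnot11, Eif3l, Cebpz and Socs1 fell under the block alone, with log2 folds between -0.59 and -0.48.

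Among end-joining genes, 0 of 9 passed over all genes by edgeR without the block, 4 passed when adjusted over the list alone, and 9 of 9 had positive log2 folds (median 0.26, camera adjusted p = 8.06e-11). Under the block Nhej1 (0.52 ± 0.09), Ercc6l2 (0.37 ± 0.07) and Prkdc (0.36 ± 0.09) rose, and the list's adjusted p = 0.0692 with an estimated correlation. The 15 measured genes of break signalling and the 53BP1 branch had a median of 0.06, with 0 called by edgeR over all genes and 0 adjusted over the list alone, or 4 adjusted over the list alone with the block. Their camera adjusted p = 0.076, or 0.0354 with the block, and adjusted p = 0.293 with the block and an estimated correlation. Within it the log2 fold was 0.25 ± 0.12 for Trp53bp1, 0.10 ± 0.13 for Rif1, -0.07 ± 0.17 for Mad2l2, 0.32 for Shld1 (listed as 1110034G24Rik), 0.29 for Shld2 (listed as Fam35a) and 0.22 for Atm. Shld3 is not among the genes of the library. The 33 Mediator genes had a median of 0.09 (camera adjusted p = 0.0118, and adjusted p = 0.0569 with an estimated correlation), with 0 called, or 4 higher (Med9, Med23, Med26 and Med19) and 1 lower under the block.

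**Figure D1:**
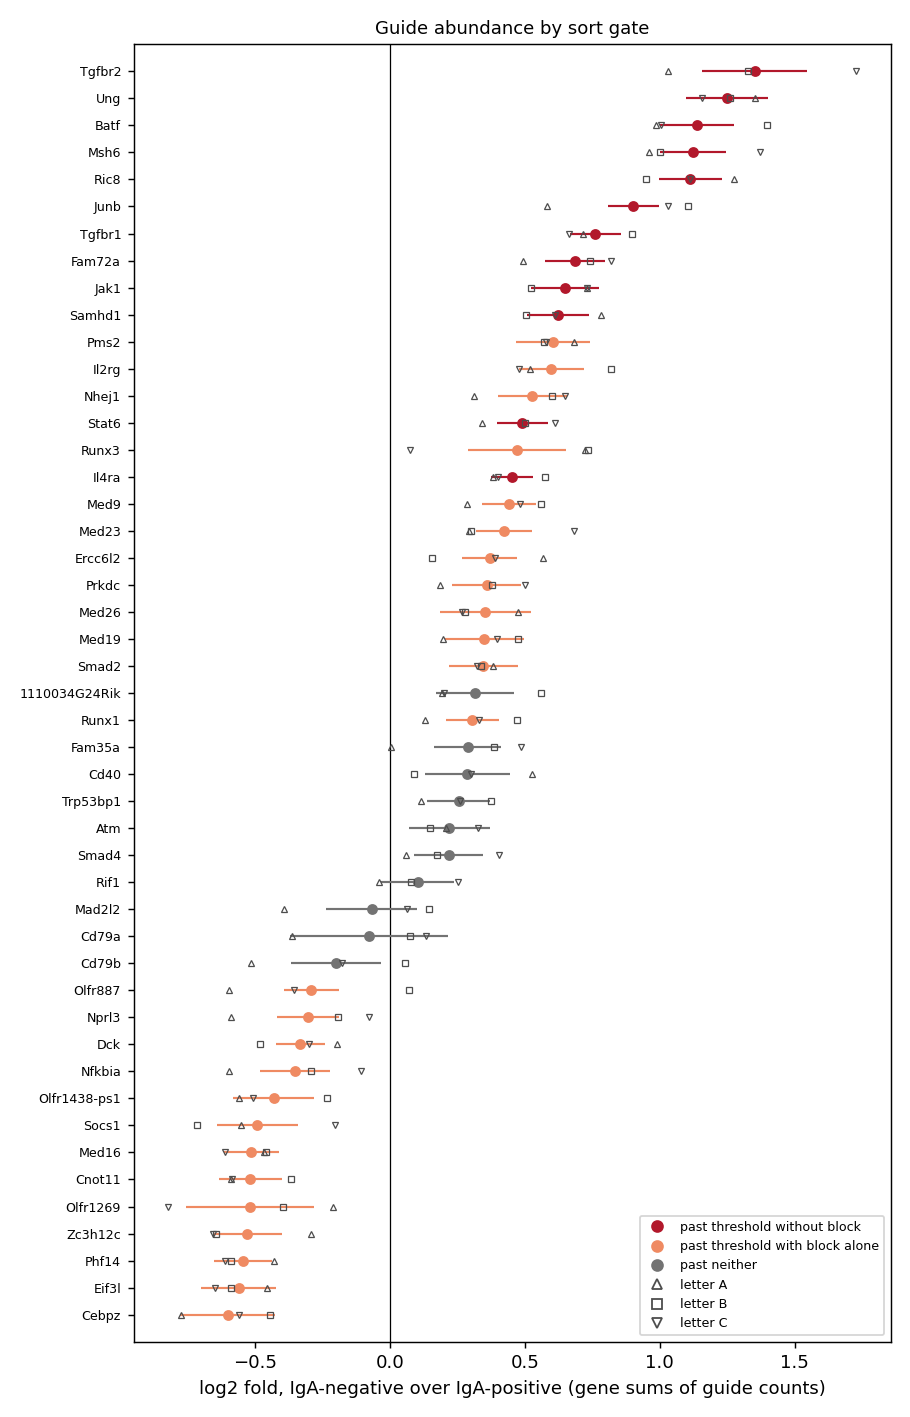
Log2 fold of guide reads per gene between IgA-negative and IgA-positive cells for genes named in the text and others of the same lists, with circles for the fitted value, bars for 1 standard error and open symbols for the replicate letters A, B and C (n = 3 per gate). Tgfbr2 lies at 1.35, Ung at 1.25 and Fam72a at 0.69, and colours show which genes passed without the replicate block, with the block alone, or neither.

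By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 27 of 19460 genes differed between the gates, 26 higher and 1 lower in IgA-negative cells. With the replicate letter as a block, all 27 remained and 160 genes differed, 106 higher and 54 lower. Fitted on the libraries of the 2 gates alone, the block gave 103 genes, 76 higher and 27 lower. Without the block, the calls for the lists above held with an estimated correlation (adjusted p between 0.000896 and 0.0046), except Mediator, and with the block the end-joining list lost its call too. The 27 became 11 without IgA-positive replicate C, 12 without IgA-negative replicate B and 13 without IgA-negative replicate C. Ung, Msh6, Tgfbr1, Tgfbr2, Batf, Junb, Ric8, Ambra1 and Mkln1 passed in every fit that left out 1 library, and the last 2 were named after their values were seen. The p-values measure the spread between libraries, since the labels do not say whether replicates were separate cultures. By guide, 12 of 93530 differed, 11 higher and 1 lower, in 7 genes. Under the block 138 guides did, 104 higher and 34 lower, in 91 genes, and 0 of 386 tested control guides were called by edgeR with or without it (4 at unadjusted p below 0.05 without it, median log2 fold -0.01). So few of all guides were called that 0 control calls were likely in any case. The test without the block was also conservative, so neither count shows that control guides were unchanged.

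Other lists did not pass. Median log2 folds were -0.01 for 21 homologous recombination and Fanconi genes, 0.03 for 8 inhibitory TGF-beta genes, -0.08 for 9 B-cell receptor genes, -0.04 for 14 elongation and exosome genes and -0.04 for 10 cohesin genes. The B-cell receptor genes Cd79a (-0.08 ± 0.29) and Cd79b (-0.20 ± 0.17) did not pass. Medians were -0.04 for 75 cytosolic ribosomal protein genes, 0.01 for 39 proteasome genes, -0.01 for 11 RNA polymerase II genes, 0.03 for 74 mitochondrial ribosomal genes and -0.01 for 36 complex I genes. Genes the line is not thought to need had medians of -0.0017 for 936 olfactory receptors, -0.0027 for 169 vomeronasal receptors and -0.03 for 20 genes of other lineages. The mean and the test had the opposite sign to the median for growth suppressors (median -0.04, mean 0.01), nucleotide pool genes (-0.04 and 0.01), activating CD40 and NF-kappaB genes (-0.01 and 0.01), RNA polymerase II (-0.01 and 0.02), complex I (-0.01 and 0.01) and vomeronasal receptors (-0.0027 and 0.007). They also did for the 9 inhibitory CD40 and NF-kappaB genes (median 0.05, mean -0.04), of which Nfkbia fell under the block (-0.34 ± 0.07, adjusted p = 0.0032).

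The comparison of IgA-positive with unsorted cells, which the study's design names, asked which knockouts were depleted from switched cells. Guides against Tgfbr2 (log2 fold -1.10 ± 0.19, n = 3, adjusted p = 0.0432), Ung (-0.97 ± 0.15, adjusted p = 0.0126) and Batf (-0.89 ± 0.14, adjusted p = 0.0126) fell. So did those against Msh6 (-0.74 ± 0.12, adjusted p = 0.0251), Junb (-0.66 ± 0.09, adjusted p = 0.0106) and Tgfbr1 (-0.62 ± 0.09, adjusted p = 0.0126). Fam72a had a log2 fold of -0.44 ± 0.11 (adjusted p = 1) and fell under the block (-0.44 ± 0.09, adjusted p = 0.0041). Under the block Ric8 (-0.64 ± 0.07), Il2rg (-0.50 ± 0.08), Jak1 (-0.39 ± 0.08), Il4ra (-0.33 ± 0.06), Stat6 (-0.33 ± 0.07), Pms2 (-0.33 ± 0.07) and Smad4 (-0.25 ± 0.06) also fell, while Phf14, Asxl2, Id2 and Med16 rose by log2 folds of 0.24 to 0.34. Of the calls under the block, 0 of 4 higher and 13 of 41 lower were kept without each letter, and DESeq2 with the block called 0 genes higher and 28 lower.

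As sets, 5 lists were lower in IgA-positive cells and kept this with an estimated correlation. Interleukin-4 genes had a median of -0.33 (camera adjusted p = 8.43e-20), with 0 of 5 called over all genes by edgeR, 4 adjusted over the list alone and 4 under the block. Activating TGF-beta genes had a median of -0.25 (adjusted p = 1.59e-17), with 2 of 8 lower over all genes, 3 adjusted over the list alone and 4 under the block. Mismatch repair genes had a median of -0.21 (adjusted p = 1.51e-14), with 1 of 8 lower, 4 adjusted over the list alone and 4 under the block. Uracil excision and related genes had a median of -0.06 and a mean of -0.27 (adjusted p = 4.33e-13), with 2 of 9 lower both over all genes and adjusted over the list alone. End-joining genes had a median of -0.21 (adjusted p = 2.62e-09), with 0 of 9 lower by edgeR, 0 adjusted over the list alone, and adjusted p = 0.0829 with the block and an estimated correlation. Mediator genes had a median of -0.05 (adjusted p = 0.0142, and adjusted p = 0.0616 with an estimated correlation). Median and mean had opposite signs for homologous recombination, inhibitory CD40 and NF-kappaB, elongation and exosome, nucleotide pool and proteasome genes, none of which passed as a list.

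By edgeR, 8 of 19460 genes passed in this comparison, all lower in IgA-positive cells, and 45 with the replicate block (4 higher and 41 lower, the 8 included). The 8 became 4 without IgA-positive replicate A, and 3 without IgA-positive replicate B, IgA-positive replicate C or unsorted replicate B. Leaving out 1 library ended the call of Msh6 in 6 of 6 fits, of Batf in 5 of 6, and of Junb, Tgfbr1, Tgfbr2 and Ung in 3 of 6. By guide, 3 passed (lower, in 2 genes), and 35 with the block (lower, in 20 genes). The count of 3 guides became 0 without IgA-positive replicate A or C or unsorted replicate A or B.

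In IgA-negative against unsorted cells, 0 genes passed by edgeR without the block (86 at unadjusted p below 0.05, 1 gene by DESeq2, 1 by combined guide z and 0 by a rotation test over guides). The 86 of 19460 genes are a share well under 0.05, so the test without the block was conservative here. It kept the spread between letters in its error, so the 0 calls do not show that effects were absent. With the block, edgeR gave 852 of 19460 genes at unadjusted p below 0.05. That is still a share under 0.05, so it is no excess of small p-values. Under the block 8 genes passed, 5 higher and 3 lower. Among the higher were Ric8 (0.48 ± 0.06, adjusted p = 7.06e-06), Gna13, a G protein alpha subunit (0.40 ± 0.08, adjusted p = 0.0448), and Ambra1, an autophagy and cyclin D regulator (0.27 ± 0.05, adjusted p = 0.0103). Among the lower were Phf14 (-0.28 ± 0.06, adjusted p = 0.0448) and Rfx5, a regulator of MHC class II genes (-0.25 ± 0.05, adjusted p = 0.0448). Without each letter, 3 of the 5 higher and 0 of the 3 lower calls were kept, and with thinned libraries 5 genes were higher and 0 lower under the block. Fam72a had a log2 fold of 0.24 ± 0.11 (adjusted p = 1, and 0.941 under the block). By guide, 0 of 93530 passed by edgeR (243 at unadjusted p below 0.05, 0 by DESeq2), or 1 lower under the block.

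The list tests of this comparison were lost with an estimated correlation. Mismatch repair genes had a median of 0.20 (camera adjusted p = 5.40e-08, and adjusted p = 0.0594 with an estimated correlation), with 1 of 8 higher adjusted over the list alone. Interleukin-4 genes had a median of 0.12 (adjusted p = 0.00031, and adjusted p = 0.0617 with an estimated correlation). Activating TGF-beta genes had a median of 0.09 (adjusted p = 0.0191, and adjusted p = 0.235 with an estimated correlation). Cytosolic ribosomal genes had a median of -0.06 (adjusted p = 0.0191, and adjusted p = 0.064 with an estimated correlation). Uracil excision and related genes had a median of -0.03 but a mean of 0.08 and a test towards higher values (adjusted p = 0.0263, and adjusted p = 0.167 with an estimated correlation), with 1 of 9 passing when adjusted over the list alone. The test and the median also had opposite signs for growth suppressor, nucleotide pool, proteasome and RNA polymerase II genes, and mean and median for olfactory and vomeronasal receptors, none of which passed.

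The comparisons with unsorted cells share the unsorted libraries. Their log2 folds correlated across genes with r = 0.141 over 19460 genes, which are not independent replicates, against r = 0.443 (0.429 to 0.455 over 20 draws) in simulated groups without any effect that shared 1 dispersion per guide. The covariance was 0.0011, against 0.0032 simulated, a difference of -0.0021, and the share of genes with the same sign was 56.4%, against 64.7%. That simulation gave unsorted libraries more spread than was observed (log2 variance after group and letter means 0.0091, against 0.0042 observed) and gates less (0.0123 and 0.0125, against 0.014 and 0.0172). With the spread of each group matched, added after seeing the data, the simulated r was 0.218 (0.205 to 0.233 over 20 draws), the covariance 0.0014, a difference of -0.000301, and the share 56.9%. The observed r lay below these draws too, and neither difference is read as an effect. Under the block, 4 of the 5 genes higher in IgA-negative cells were among the 41 lower in IgA-positive cells, Ric8 and Ambra1 among them. In each of the 20 draws with the block and the spread of each group matched, 0 genes were called in both comparisons. Those draws called at most 0 genes for IgA-negative against unsorted, so their overlap had to be 0. It is therefore no measure for the observed 4. The unsorted libraries are too few to split with at least 2 on each side.

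**Figure D2:**
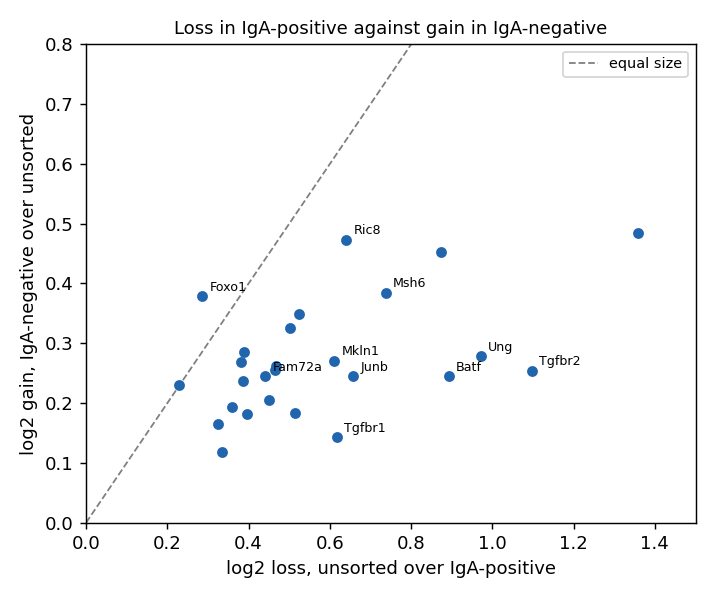
Log2 loss of guide reads in IgA-positive cells (unsorted over IgA-positive) against log2 gain in IgA-negative cells (IgA-negative over unsorted) for the 26 genes called higher in IgA-negative than in IgA-positive cells, with a dashed line at equal size. With loss on the horizontal axis, points below the line have a loss above their gain, as in 24 of 26 genes. Fam72a had a loss of 0.44.

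The comparison of T9 unsorted cells with T0 shows guide loss or gain between these labels. The T9 cells had 3 days with the cocktail, whereas the T0 cells were untreated. Time in culture and exposure to the cocktail therefore cannot be told apart in these ratios. That includes the ratios of genes in the cocktail's own pathways, such as Tgfbr1 and Smad4. The comparison has 1 T0 library, so no test was made, and values are mean log2 ratios with the SD over 3 unsorted libraries. The lowest named ratios were for Ssu72 (-1.40 ± 0.47), Hsd17b10 (-1.37 ± 0.21), Cstf1 (-1.36 ± 0.07) and Dohh (-1.27 ± 0.28), followed by Ppcs, Tamm41, Preb and Actr3 (-1.26 to -1.23). Among the highest were Rap2c (0.91 ± 0.16), Ipo8 (0.86 ± 0.10), Smad4 (0.80 ± 0.20), and Ambra1 (0.79 ± 0.13), with Map4k4, Tgfbr1 and Pepd at 0.70 to 0.72. Trp53 was at 0.06 ± 0.11. All guides and all 3 libraries were lower for 2064 genes and higher for 950.

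Mitochondrial ribosomal genes (median -0.70), complex I (-0.58), cohesin (-0.55), break signalling (-0.51), elongation and exosome (-0.50), activating CD40 and NF-kappaB (-0.49), homologous recombination (-0.39), cytosolic ribosomal (-0.31), proteasome (-0.24) and Mediator genes (-0.22) lay below each of 10000 random lists matched on T0 abundance. B-cell receptor genes (-0.57) lay at percentile 0.01, end-joining genes (-0.30) at 0.22, nucleotide pool genes (-0.27) at 0.38, interleukin-4 genes (-0.16) at 2.60 and RNA polymerase II genes (-0.17) at 3.14. Activating TGF-beta genes (0.38), olfactory receptors (0.07) and vomeronasal receptors (0.06) lay at percentile 100, and growth suppressors (0.11) at 99.8. The activating TGF-beta list was split, with 4 of 8 genes above nearly all olfactory receptors and 2 below nearly all. Its medians in the 3 libraries ran from 0.16 to 0.53. When ratios were centred on olfactory receptors, that list's median was -0.000598 by construction. Cytosolic ribosomal genes had a median of 1044 reads at T0, 0.588 of that of olfactory receptors, so part of their loss, or a lower starting amount, preceded T0.

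**Figure D3:**
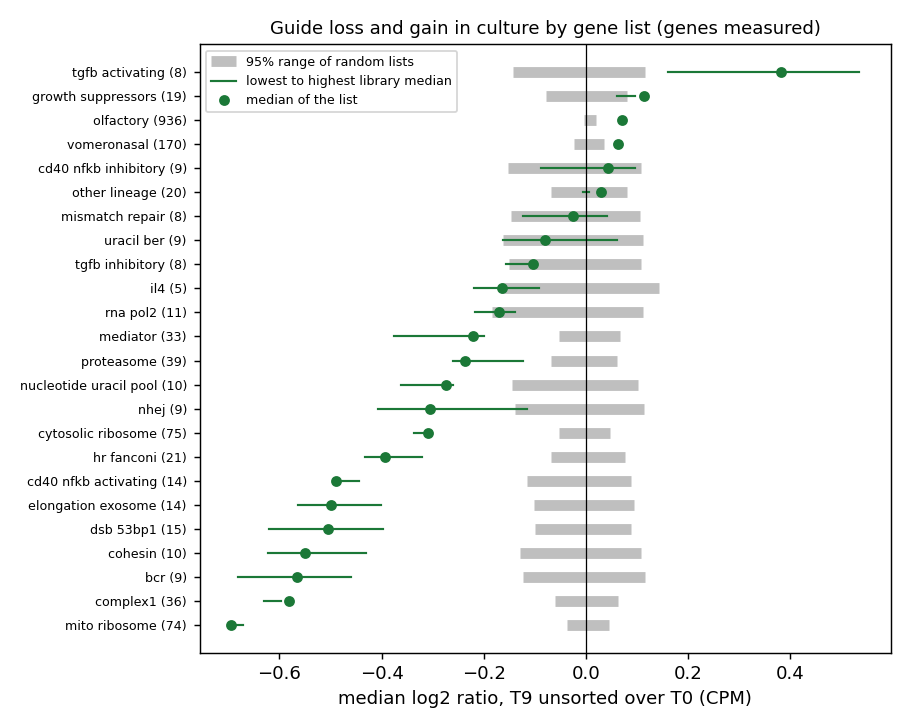
Median log2 ratio of guide reads (CPM) in T9 unsorted cells over T0 for each gene list, with dots for the list's median, lines from the lowest to the highest of the medians of 3 libraries and grey bars for the 95% range of random lists matched on T0 abundance. Mitochondrial ribosomal genes lie lowest at -0.70 and activating TGF-beta genes highest at 0.38. T9 cells had the cocktail and T0 cells did not, so its effect is not separated from time in culture.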

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

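The thinned libraries, the alternatives to the blocked fit and the estimated correlation within that fit were chosen after the data were seen. Over 2070 values of named genes in the 3 comparisons of T9 libraries, 1849 kept the call or its absence, 94 lost the call, 127 gained it and 0 reversed a call. Over 720 list values in these comparisons, 671 kept the call or its absence, 43 lost and 6 gained it. Where a value below differs from the reported one, the cause was not tested.

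With the replicate block (paired by letter), genes called were 8 for IgA-negative against unsorted, 45 for IgA-positive against unsorted and 160 between the gates, in place of 0, 8 and 27, and with a guide GC correction 9, 42 and 151. Guides called were 1, 35 and 138 in place of 0, 3 and 12. The block ended no call of a named gene or list, and among lists it added only the call of break signalling genes between the gates (adjusted p = 0.0354), which was lost with an estimated correlation (adjusted p = 0.293). DESeq2 called 1, 13 and 42 genes, and 12 and 33 guides in the comparisons with 3 and 12. Combined guide z called 1 and 13 genes in the comparisons with unsorted cells. The rotation test over guides called 0 of the 8 and 3 of the 27. Removing the most abundant guide left 4 of the 8.

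Leaving out 1 library gave 3 to 7 genes for IgA-positive against unsorted (4 without IgA-positive A, 3 without IgA-positive B or C or unsorted B) and 11 to 23 between the gates (11 without IgA-positive C, 12 without IgA-negative B, 13 without IgA-negative C). It gave 0 to 2 guides in place of 3 (0 without IgA-positive A or C or unsorted A or B) and 4 to 9 in place of 12 (4 without IgA-positive C, 5 without IgA-positive B, and 6 without any of the IgA-negative libraries). Fam72a lost its call between the gates in 4 of 6 such fits, Stat6 in 6 of 6, and no gene with a call changed sign. Some named genes without a call did, Rif1 among them.

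In the paired fit, DESeq2 called 5, 28 and 83 genes in place of 8, 45 and 160, and a fit of only the 2 groups compared called 18, 75 and 103. For IgA-negative against unsorted, 4 remained without the most abundant guide and 5 were called with thinned libraries. Leaving out a letter gave 3 to 8 (3 without B, 4 without C), 19 to 32 (19 without B, 21 without C) and 81 to 113 genes (81 without B, 93 without C). Of the 106 higher and 54 lower genes between the gates, 41 and 11 passed without each letter.

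For T9 against T0, 54 of 168 list values moved (13 of 24 centred on olfactory receptors, 10 of 24 from guide medians, 5 to 7 of 24 without a library), and of 119 gene values 6 moved and 1 reversed. The median of cytosolic ribosomal genes was -0.31, and -0.29 with library totals, -0.38 centred on olfactory receptors, -0.26 with a prior of 5, and -0.33 to -0.30 without a library. That of olfactory receptors was 0.07, and 0.0936, -0.000598 and 0.0639 in those 3 settings, 0.0788 from guide medians, and 0.0654 to 0.0734 without a library. Trp53, the value that reversed, went from 0.06 to -0.0145 when centred on olfactory receptors. No paired analysis was possible because T0 has 1 library. At these depths the test without the block recovered 0 of 68 simulated genes changed 1.2-fold between the gates and 51.5% of those changed 1.5-fold, and 27 of 68 changed 1.2-fold with the block. The simulated gates had less spread than the observed ones, so these recoveries may be too high.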

Other observations

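The gene groups and tests in this part were chosen after the results were seen, except the test of growth and the splits of the libraries, which were written before. Some genes outside the fixed lists also passed between the gates, where 106 of 19460 genes were higher under the block. They are grouped here by known function, after their values were seen and without a test of the groups. In the CTLH ubiquitin ligase complex, Mkln1 passed without the block (log2 fold 0.88 ± 0.13, edgeR adjusted p = 0.004). The 12 measured genes are of this complex and Ube2h, a ubiquitin-conjugating enzyme that works with the complex. Under the block 5 of the 12 were higher in IgA-negative cells: Mkln1, Maea (0.73 ± 0.07, adjusted p = 3.71e-12), Ube2h (0.42 ± 0.07), Gid8 (0.37 ± 0.08) and Wdr26 (0.32 ± 0.07). The others did not pass. Among 32 G protein subunit genes, Gng5 passed without the block, and Gnas (0.83 ± 0.07), Gng5 (0.73 ± 0.09), Gna13 (0.67 ± 0.09) and Gnb2 (0.45 ± 0.07) passed with it. Their chaperones Ric8 and Pdcl (0.62 ± 0.09) and, of 10 adenylyl cyclase genes, Adcy7 (0.58 ± 0.08) passed under the block too. Among 7 genes around PI3-kinase, Foxo1 (0.67 ± 0.09) and Ppp2r2a (0.65 ± 0.08) passed with or without the block, and Inpp5d (0.21 ± 0.06) with it alone. Of 10 Batf and AP-1 family genes, Batf and Junb passed.

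Genes called without the block were mostly higher in IgA-negative than in IgA-positive cells. In the fit with the block 106 were higher and 54 lower. Unequal depth would need the read totals of the gates to differ, but their means differed by 0.403 of the SD within gates. A scaling error would shift all genes alike. The median of olfactory receptors between the gates was at most 0.005 in the 3 letters, against a smallest fold called higher of log2 0.45. These libraries were already scaled by TMM, which centres most genes, so this median could not show such a shift. With library totals in place of TMM and without the block, 26 genes were higher and 1 lower, so the excess of higher calls did not depend on TMM. Under the block, 0 of 106 higher calls were olfactory receptors against 5.10 for calls spread evenly over genes (two-sided Fisher exact p = 0.0102). Of the 54 lower calls 3 were, against 2.60 (Fisher exact p = 0.745). With 54 calls, even 0 olfactory receptors would not have brought p below 0.05, so this test could not exclude false calls. False calls may make up part of the lower calls, and no biological explanation was tested for them.

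The 26 genes called higher fell more in IgA-positive cells, against unsorted cells, than they rose in IgA-negative cells, in 24 of 26 genes (median loss 0.48 and gain 0.25 on the log2 scale). Unequal depth would bring the median difference near 0 after thinning, but it was 0.24 with thinned libraries and 0.21 without thinning. On the log2 scale a fall exceeds the matching rise even in an equal mixture, so the 24 of 26 alone do not point to unequal shares. A candidate explanation for the rest of the difference is that unsorted cells were a mixture with fewer IgA-positive than IgA-negative cells. Mass balance on the linear scale gave shares of 33.3%, 38.0% and 41.9% IgA-positive cells for letters A, B and C, at most 41.9%. Each share came from 1 least-squares slope over the 26 genes, in which the genes that fell most weigh most. The shares rest on the same genes and reads as the pattern, so they restate it and do not test the mixture. Error in the measured losses also lowers such a slope, so the shares may be too low. Over single genes the share was 23.0% to 62.5%, with Ric8 at 52.0% although its loss (0.64) exceeded its gain (0.47). The fraction of sorted cells in each gate was not used here, so the mixture stays a hypothesis.

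Slower growth of cells with these guides could lower their switching, since switching goes with division. It would place most of the called genes below olfactory receptors in T9 against T0, but 14 of 26 lay below and 12 above. Of the 106 higher under the block 62 lay below (median 0.03), against 67.5% of all tested genes. Tgfbr2, Ambra1 and Tgfbr1 were among the highest and Jak1 the lowest (-0.46), and the median of the 26 was 0.06 against 0.07 for olfactory receptors. Across 19460 genes, which are not independent replicates, the ratio and the fold between gates had r = 0.0005 and rho = -0.02. These values cover the called genes as a set, so slower growth stays open for single genes such as Jak1. The ratio also does not set apart division during the 3 days with the cocktail.

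Splits of the libraries into other groups were too few for a share under 0.05. Without the block, of 10 splits each, 10 gave as many genes as the real 0 for IgA-negative against unsorted, 1 as many as the real 8 for IgA-positive against unsorted and 1 as many as the real 27 between the gates, with 0 as the highest of the others. With the block, among 4 splits that part all pairs, 1 of 4 gave as many as the real 8, 45 and 160, with 0 as the highest of the others.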
